A study of Homo sapiens with 8 samples.

How the data were processed

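Genomic DNA of 4 established human cancer cell lines was profiled by whole-genome bisulfite sequencing, which reads unmethylated cytosines as thymine and leaves methylated cytosines as cytosine. A2780 and OVCAR3 are ovarian cancer lines, and H23 and H460 are lung cancer lines. Each line was represented by its cisplatin-sensitive parent and by a resistant derivative that the submitters raised from that parent under rising cisplatin doses, per the series design. There was 1 library per line and state, 8 in all. Per the labels' protocols, the DNA was spiked with unmethylated lambda phage DNA, sheared by sonication, ligated to paired-end adaptors, converted with bisulfite in 2 rounds and amplified by PCR. The conversion rate of the spike-in was not analysed here.

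The authors deposited, for each library, the methylation level of single CpG sites as a fraction between 0 and 1, with both strands merged into a single value. The genome build is GRCh37, per the submitters' processing notes. The aligner, the methylation caller, the coverage filter and any correction of the levels are not given in the sources used here. The files hold no read counts and no coverage, so the depth behind each level is unknown and no counting interval is given. A CpG absent from a library's list has no level there, and the rule by which CpGs were listed is not known. Among 100-kb windows over 20% methylated, the share of CpGs listed rose with the methylation level of the window in each library, while in H460 windows under 20% were listed at 35.3% in the resistant and 41.6% in the sensitive library, against 31.8% and 35.3% between 20 and 60%. In the sensitive OVCAR3 library it was 29.7% at the median of windows between 20 and 60% methylated and 78.0% in windows over 90%. Levels therefore describe listed CpGs, which lean away from regions of low and intermediate methylation. The list of the sensitive H23 library used here ended within a line on chromosome 2, at position 236425715. Comparisons within H23, and all comparisons over 8 libraries, were limited to chromosome 1 and chromosome 2 up to that position. Sex chromosomes were left out. Whether the files count positions from 0 or 1 is not stated in them. The first coordinate was read as counted from 0, and regions are given counted from 1.

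The planned tests assumed read counts and promoters. Because the files hold fractions only, Fisher's exact test on reads was not run, and the per-line comparisons were made by a rule of size. The gene annotation held here is on build GRCh38, which differs from that of the files, so no gene was placed or named, and 1-kb tiles with at least 40 CpG positions (called CpG-dense tiles) took the place of promoters, as planned for that case. The 20 planned lists of genes, the comparison of lncRNA with coding promoters and the genes chosen in advance were not analysed for the same reason.

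CpG positions were pooled over the 8 libraries, giving 21557160 autosomal positions. Levels were averaged over CpGs listed in both libraries of a line, over all of them and by local density, counted as CpG positions within 100 bp on either side (dense at 10 or more, intermediate at 4 to 9, sparse at 3 or fewer). Large domains were described in 100-kb windows with at least 50 CpGs outside the dense class. Tiles of 1000 bp with at least 5 CpGs in both libraries were called changed at a difference of at least 30 percentage points, and CpG-dense tiles at 20 points. With no replicate library within a line, these calls carry no p-value and compare the libraries of that line. As a check chosen after the calls were seen, differences were compared between alternate CpGs of a tile, between the CpGs of its first and last 350 bp, and between a changed tile and the tile that lies 1 kb beyond its end. Across lines, mean differences were tested with a two-sided exact sign-flip permutation test. CpG-dense tiles were tested with limma 3.58.1 on log2((level + 0.01)/(1 - level + 0.01)) with the cell line as a block, with Benjamini-Hochberg adjustment at 0.05. Overlaps of changed tiles between lines were tested with exact hypergeometric tests on tiles that had room to change by the threshold in both lines. The pairing comes from the cell line, since each derivative was made from its own parent. Deviations from the group means correlated within every pair across 4570 CpG-dense tiles, at r of 0.934 in A2780, 0.931 in H23, 0.948 in H460 and 0.908 in OVCAR3. 1 derivative of each line was profiled, so p-values of limma and of the sign-flip test across lines rest on the spread between lines. Those of the hypergeometric tests take tiles as the units. A second sign-flip permutation test, over the CpGs of a tile, was tried as an alternative within each line. Its units are CpGs, which often share reads, so it does not measure the spread between lines or cultures.

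The rule for naming regions gave, per line, the 4 CpG-dense tiles with the largest rise and the 4 with the largest fall among those with at least 10 CpGs, and the 2 largest rises and falls among 1-kb tiles with at least 20 CpGs. Across lines, it gave the 8 tiles with the smallest p in each direction. The text gives all of them for A2780 and OVCAR3, and only some for H23, for H460 and across lines. Windows of 100 kb and 1 Mb, and tiles shared by several lines, are named from the extremes and were chosen after their values were seen. In place of a coverage ratio, the share of CpG positions listed was compared in 1-Mb windows with at least 500 CpG positions, at tiles with at least 3 CpGs that were at least 90% methylated in both libraries and under 5 points apart. A window was called shifted beyond 0.5 on the logit scale after centring on the median window. This measure was chosen after a first version over all CpGs was found to follow the methylation level itself.

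The steps were tested on simulated data. For the size rule, differences were added to tiles of H460 chromosome 22 (17814 tiles). All of the tiles given 40, 60 or 80 points were called, none of those given 20 points, and 0 of 17614 unchanged tiles, which checks that the rule is applied as written and says nothing of its error in the other lines. With the sign-flip permutation test over CpGs added, 30%, 32% and 38% of the tiles given 40, 60 and 80 points were called. For limma on 4570 tiles, noise was drawn with the residual SD of real tiles taken at random, equal in every line. Of tiles changed by 1 on the log2 scale, 50% were called, 88% at 2, 96% at 3 and 100% at 4, with 8 unchanged tiles called. The comparisons, the thresholds of size, the naming rule and most other settings tried were set before the data were examined, and the closing section says which were added later. They varied the size threshold, the number of CpGs, the set of CpGs, the window width, the logit offset, the block and the lines included. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3.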

Results

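DNA methylation was compared between cisplatin-sensitive parents and their cisplatin-resistant derivatives in A2780 and OVCAR3 ovarian cancer cells and in H23 and H460 lung cancer cells. Cisplatin is a platinum drug that crosslinks DNA. The series title gives the aim as finding lncRNAs that differ in resistant cells, by way of their epigenome. Methylation levels were held for 16631364 CpGs in the resistant and 16617892 in the sensitive A2780 library, 17508299 and 16082492 in OVCAR3, and 12966919 and 13380494 in H460. In H23 they were held for 14752386 CpGs in the resistant library and 2550157 in the sensitive library, the latter from chromosome 1 and most of chromosome 2 only. The read depth is unknown. Each line had 1 resistant and 1 sensitive library, so differences within a line have no replicate check. Positions are on GRCh37, and no gene annotation was applied to them.

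Each library resembled the other library of its own line most. Across 103154 tiles of chromosomes 1 and 2, Pearson's r across tiles between the libraries of a line was 0.969 in A2780, 0.975 in H23, 0.980 in OVCAR3 and 0.988 in H460. Correlations with libraries of other lines lay between 0.722 and 0.820. Tiles are not independent replicates, so these values describe the libraries.

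The first comparison asked whether resistant cells differed from their parents in overall methylation. The resistant OVCAR3 library was more methylated than its parent, at 89.1% against 87.7% over 14709047 CpGs, a difference of 1.39 points, and it was higher on 22 of 22 autosomes. H23 also had the higher level in the resistant library, by 1.17 points (87.3% against 86.2%, over 2221373 CpGs). In A2780 the levels were 82.9% and 82.7%, a difference of 0.210 points, with 17 of 22 autosomes higher. H460 went the other way, from 81.7% in the parent to 81.6% in the derivative, a difference of -0.137 points, with 18 of 22 autosomes lower.

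The chromosomes of OVCAR3 ranged from 0.911 points on chromosome 13 to 2.20 points on chromosome 20, while those of A2780 ranged from -0.555 points on chromosome 4 to 0.705 points on chromosome 18. In OVCAR3 the share of CpGs between 20 and 80% methylated was 5.51% in the parent and 3.88% in the derivative, and the share above 80% was 87.4% and 89.3%. On the part of chromosomes 1 and 2 held for all lines, the resistant libraries were higher by 0.640 ± 0.683 points (SD, n = 4 lines), with 3 of 4 lines higher. This was within the spread between lines (two-sided exact sign-flip permutation p = 0.25, where the smallest p possible is 0.13). Over all autosomes in the 3 lines other than H23, the difference was 0.488 ± 0.801 points (SD, n = 3; exact permutation p = 0.5, smallest possible 0.25).

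**Figure D1:**
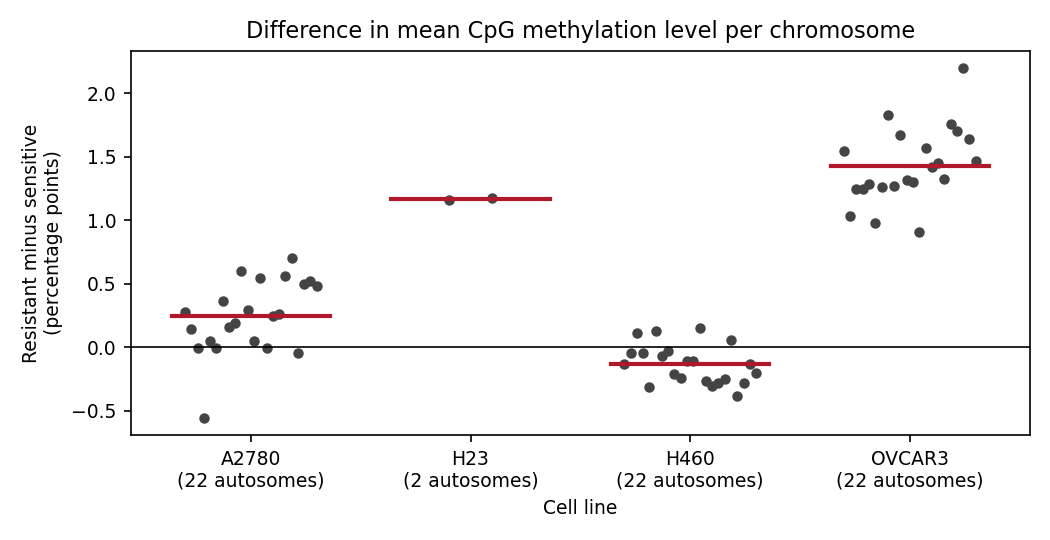
Difference in mean methylation between the resistant and the sensitive library, in percentage points, with a point for each autosome of each cell line and a red line at the mean over chromosomes. OVCAR3 lies between 0.911 and 2.20 points, H460 between -0.385 and 0.155 points, and H23 has 2 chromosomes.

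By local CpG density, the OVCAR3 difference was present in every class. CpGs in dense surroundings were at 64.5% in the resistant and 62.9% in the sensitive library, a difference of 1.62 points, and CpGs in sparse surroundings differed by 1.36 points. H23 differed by 0.721 points in dense and 1.40 points in sparse surroundings. A2780 differed by 0.459 points in dense surroundings and by 0.000466 points in sparse ones. H460 was lower by contrast in dense surroundings (63.8% against 64.4%, a difference of -0.575 points) and differed by 0.209 points in sparse ones. Across the 4 lines, on the shared part of chromosomes 1 and 2, sparse CpGs were higher in 4 of 4 resistant libraries (0.744 ± 0.712 points, SD, n = 4; exact permutation p = 0.13, the smallest possible). Dense CpGs differed by 0.508 ± 0.803 points (SD, n = 4; exact permutation p = 0.375).

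Large domains of low methylation covered different shares of the lines. In A2780, 23.7% of 26009 windows of 100 kb were below 60% methylated in the resistant library and 22.6% in the sensitive library. The shares were 10.5% and 10.7% in H460, 5.48% and 6.27% in OVCAR3, and 3.59% and 3.10% in H23. In A2780, 1044 windows were higher by at least 10 points in the resistant library and 760 were lower, so domains changed in both directions. OVCAR3 had 688 such windows higher and 54 lower, H23 had 1 higher and 30 lower, and H460 had 1 higher and 7 lower. Over windows of any difference the balance was not the same. In H23, 85.7% of windows were higher in the resistant library, with a median difference of 1.14 points, and in A2780 40.1% were higher, with a median of -0.315 points. The shares were 90.9% in OVCAR3 and 48.6% in H460.

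The widest domain differences were in OVCAR3. The window chr17:31500001-31600000 was at 35.2% in the parent and 95.0% in the derivative, chr7:131700001-131800000 at 13.9% and 69.0%, and chr10:128300001-128400000 at 13.2% and 67.5%. These windows rest on 50, 89 and 138 CpGs, so the widest difference lay at the minimum of 50 CpGs for a window. In A2780, chr1:210600001-210700000 was at 38.2% in the parent and 79.1% in the derivative, next to chr1:210500001-210600000 at 48.9% and 82.7%. In the other direction, chr15:47800001-47900000 was at 67.3% and 38.9% in A2780, chr2:83000001-83100000 at 71.6% and 51.1% in H23, and chr7:137000001-137100000 at 71.2% and 51.3% in OVCAR3.

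The next comparison asked which local regions differed within each line. A2780 had 2804 tiles of 1 kb higher in the resistant library and 1330 lower by at least 30 points, of 1008207 tested. OVCAR3 had 2201 higher and 384 lower of 1060103. H23 had 82 higher and 67 lower of 159451 in the part held, and H460 had 2 higher and 13 lower of 783363. Of the changed tiles, 67.8% were higher in A2780, 85.1% in OVCAR3 and 55.0% in H23. Centred on the median difference of the tiles, which is 1.02 points in H23, that line had 66 higher and 74 lower tiles, or 47.1% higher, so its direction turned. Counts moved by more than 1.5 times with the size threshold, the number of CpGs required and a sign-flip permutation test over CpGs. That test left 608 higher and 194 lower tiles in A2780, and 456 and 69 in OVCAR3. Higher tiles outnumbered lower ones in A2780 and OVCAR3 under each alternative run.

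Differences found at the first end of a tile were smaller at its other end. Among tiles chosen for a difference of at least 30 points at the CpGs of their first 350 bp, a choice that by itself favours a smaller value elsewhere, the CpGs of the last 350 bp, at least 300 bp away, differed in the same direction in 87.3% of tiles in A2780 and 79.9% in OVCAR3. The median difference there was 11.9 points in A2780 (1379 tiles) and 4.64 points in OVCAR3 (1045 tiles). For OVCAR3 tiles that were lower at the first end it was 0.827 points, and it was 2.89 points in H23 and 1.57 points in H460. Tiles higher at the first end were also higher at the last in 90.1% in A2780, against 53.9% of steady tiles at the same level. In OVCAR3 these shares were 85.2% and 65.3%. For lower tiles they were 77.8% and 46.0% in A2780, and 63.5% and 35.9% in OVCAR3. Over both directions, 74.6% of 71 tiles in H23 and 71.4% of 14 in H460 moved the same way. A fragment selected at up to 300 bp, per the labels' protocols, would hardly reach from end to end, so the ends rest on largely separate reads.

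**Figure D2:**
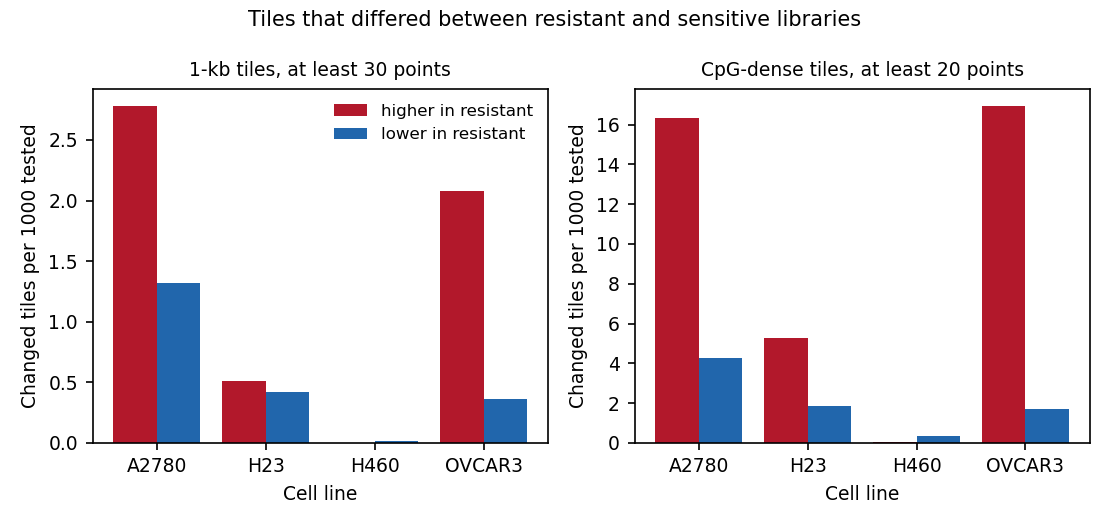
Tiles called higher or lower in the resistant library per 1000 tiles tested, for 1-kb tiles (at least 30 points, left) and CpG-dense tiles (at least 20 points, right) in each cell line, with separate vertical axes. Among CpG-dense tiles, 16.3 per 1000 were higher in A2780 and 16.9 in OVCAR3, against 5.28 in H23 and 0.0603 in H460.

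CpG-dense tiles were also mostly higher in the resistant libraries of A2780 and OVCAR3. In A2780, 552 of 33795 were higher and 144 lower by at least 20 points, and in OVCAR3 562 of 33163 were higher and 57 lower. H23 had 26 higher and 9 lower of 4924, and H460 had 2 higher and 12 lower of 33160. The size threshold was lower for CpG-dense tiles than for 1-kb tiles, so the rates of these sets are not on the same scale.

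In A2780, several CpG-dense tiles went from nearly unmethylated to mostly methylated. The tile chr1:27854001-27855000 was at 7.82% in the parent and 76.9% in the derivative over 32 CpGs, a difference of 69.1 ± 2.82 points (SE over CpGs, which leaves out variation between cultures and noise shared by CpGs on the same reads). The tile chr2:219738001-219739000 rose from 10.6% to 78.6%, chr17:77808001-77809000, in a region listed more fully in the resistant library, from 5.94% to 70.8%, and chr19:11529001-11530000 from 16.8% to 81.1%. Among losses, the CpG-dense tile chr4:134073001-134074000 fell from 92.8% to 13.2%, chr4:189027001-189028000 from 96.7% to 17.3%, chr13:60968001-60969000 from 83.2% to 4.19%, and chr11:77184001-77185000 from 82.5% to 6.24%. The last of these rests on 12 of its 58 CpG positions, and the rise at chr17:77808001-77809000 on 20 of 76. The largest fall among 1-kb tiles with at least 20 CpGs was that of chr8:90913001-90914000, from 92.2% to 4.88%.

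OVCAR3 gained methylation at chr13:43148001-43149000, from 22.1% to 97.1%, at chr4:16084001-16085000, from 7.15% to 82.0%, at chr22:50982001-50983000, from 24.6% to 95.1%, and at chr7:27204001-27205000, from 36.6% to 96.4%. It lost methylation at chr4:30724001-30725000, from 71.2% to 3.43%, at chr1:109816001-109817000, from 86.1% to 32.8%, at chr2:45165001-45166000, from 50.8% to 2.82%, and at chr7:27163001-27164000, from 68.7% to 20.9%. The tiles on chromosome 4 lay in a region where the resistant library listed relatively fewer CpGs at steady tiles. The tile chr13:43148001-43149000 rests on 10 of its 66 CpG positions, with an SE over CpGs of 8.39 points, and chr1:109816001-109817000 on 14 of 40.

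In H23, chr1:99470001-99471000 rose from 30.2% to 85.1%, chr1:98519001-98520000 from 45.8% to 89.1%, and chr1:19029001-19030000 from 15.4% to 58.1%. The adjacent tiles chr2:38301001-38302000 and chr2:38302001-38303000 fell from 95.3% to 55.9% and from 76.5% to 29.1%, and chr2:55450001-55451000 fell from 58.8% to 25.5%. In H460, chr6:48036001-48037000 rose from 32.5% to 58.9% and chr6:78173001-78174000 from 33.3% to 58.6%, while chr11:87908001-87909000 fell from 38.2% to 14.5% and chr11:65325001-65326000 from 69.3% to 46.2%. The H23 tiles at chr1:98519001-98520000 and chr1:99470001-99471000 also lay where the resistant library listed relatively fewer CpGs. Some tiles rest on few of their CpG positions: chr1:99470001-99471000 on 12 of 86 in H23, and chr6:78173001-78174000 on 10 of 61 and chr11:65325001-65326000 on 14 of 60 in H460.

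Changed tiles of A2780 and OVCAR3 gathered in particular regions. In A2780, 74 of 271 tested tiles of chr18:22000001-23000000 were higher in the resistant library, and the mean level of the window was 67.3% in the parent and 86.9% in the derivative. Its steady tiles had 91.6% of CpGs listed in the resistant and 85.9% in the sensitive library, a shift of 0.644 on the logit scale. The window chr1:210000001-211000000 held 63 higher tiles. Windows of 1 Mb with at least 20 higher tiles numbered 15 in A2780 and held 494 tiles, or 17.6% of those that were higher. OVCAR3 had 17 such windows with 539 tiles, led by chr1:13000001-14000000 with 54 of 135 tested tiles (37.7% in the parent, 64.8% in the derivative), chr10:128000001-129000000 with 48 and chr10:122000001-123000000 with 47. Among lower tiles of A2780, chr19:22000001-23000000 held 30, with a mean level of 92.1% in the parent and 76.8% in the derivative. At its steady tiles 82.4% of CpGs were listed in the resistant and 91.9% in the sensitive library, a shift of -0.813 on the logit scale. Of the windows with at least 20 changed tiles where listing could be measured, the listed share was shifted in 4 of 12 with higher and 1 of 2 with lower tiles in A2780, and in 1 of 15 with higher tiles in OVCAR3. It could not be measured in chr1:210000001-211000000 of A2780 or in chr1:13000001-14000000 of OVCAR3.

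In 100 random draws of tiles matched on the level in the parent, the fullest window held 22 higher tiles for A2780 and 27 for OVCAR3, and no draw reached the observed 74 and 54. For lower tiles the fullest windows held 30 in A2780 against 9 in the draws, and 7 in OVCAR3 against 5. In H23 the higher tiles did not gather beyond the draws, with 3 in the fullest window and as many in 69 of 100 draws, while its lower tiles reached 7 against 4 in the draws.

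**Figure D3:**
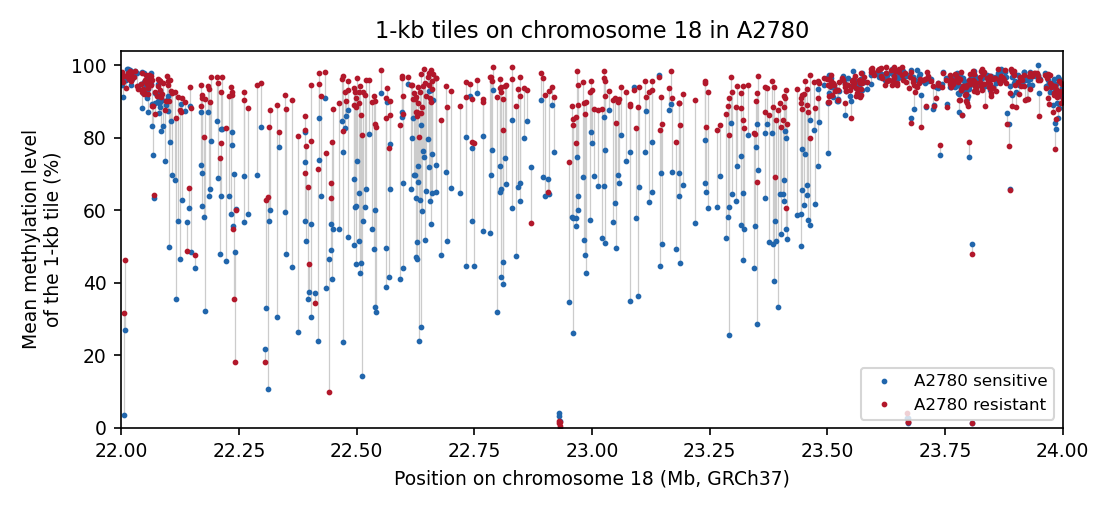
Methylation of 1-kb tiles along the most changed part of chromosome 18 in the sensitive and the resistant A2780 library, in percent against position in Mb from 22 to 24 Mb, with grey lines joining the libraries of a tile. Over chr18:22000001-23000000 the mean is 86.9% in the resistant and 67.3% in the sensitive library, while some tiles are nearly equal and a few are lower in the resistant library, such as chr18:22442001-22443000 (46.6% in the sensitive and 9.80% in the resistant library). Higher tiles also lie beyond that window.

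The design also asks whether the same regions differed between derivative and parent in different lines. A derivative can differ from its parent in more than resistance, and this design cannot tell these apart. Among CpG-dense tiles that had room to rise in both A2780 and OVCAR3 (16218 tiles), 373 were higher in A2780, 270 in OVCAR3, and 35 in both, where independent lists would share 6.21 (exact hypergeometric test, Benjamini-Hochberg adjusted p = 9.56e-16). Shared tiles included chr14:104800001-104801000, at 31.5% in the parent and 81.7% in the derivative of A2780 and 26.7% and 56.3% in OVCAR3, and chr2:177039001-177040000, at 48.1% and 71.8% in A2780 and 9.76% and 68.9% in OVCAR3. No CpG-dense tile was lower in both, where 0.210 would be shared. A2780 and H23 shared 3 higher tiles against 0.206 for independent lists (adjusted p = 0.0053, exact hypergeometric test). Over the 3 lines other than H23, 36 tiles were higher in at least 2 lines and 1 was lower, chr10:5734001-5735000 in H460 and OVCAR3, and none was called in 3 lines.

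Neighbouring tiles are not independent, so these p-values are too small: the 36 shared tiles fell into 19 loci when tiles up to 100 kb apart were joined. The expected overlaps were also not matched on the level in the parent. Higher CpG-dense tiles started at a median of 37.5% in A2780 and 46.1% in OVCAR3. Tiles at intermediate levels in both parents could therefore be shared by chance more often than the expected values allow. For 1-kb tiles at 30 points, A2780 and OVCAR3 shared 18 higher tiles against 9.61 (adjusted p = 0.0884, exact hypergeometric test). At 30 points, 3 CpG-dense tiles were higher in at least 2 of the 3 lines. Across all 103154 tiles of chromosomes 1 and 2, differences correlated between lines at Pearson's r from -0.00485 to 0.0281.

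The paired limma test of CpG-dense tiles over the 4 lines called no tile. On the shared part of chromosomes 1 and 2, 4570 tiles were tested, 0 passed in either direction, and the smallest Benjamini-Hochberg adjusted p from limma was 0.856. At an unadjusted p under 0.05 limma gave 108 higher and 39 lower tiles. Together these 147 tiles are fewer than evenly spread p-values would give on average. Against splits of the libraries that part every pair they are no shortfall, as 3 of 8, the real split included, gave as many. Without H23, limma gave 52 higher and 55 lower, so the balance turned. The tile with the smallest p, chr1:64881001-64882000, was higher in the resistant library by 5.99 points in A2780, 1.76 in H23, 2.90 in H460 and 2.25 in OVCAR3, a limma log2 difference of 0.93 ± 0.17 (SE; limma adjusted p = 0.856). Others with small p were chr1:3102001-3103000, higher by 6.58 ± 3.10 points (SD, n = 4), and chr1:6507001-6508000, higher by 14.5 ± 14.3 points. With a lower level, chr2:176969001-176970000 differed by -7.65 ± 4.57 points and chr2:177872001-177873000 by -2.17 ± 0.219 points (SD, n = 4).

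Over all autosomes in the 3 lines other than H23, limma called 0 of 31181 tiles, with 450 higher and 274 lower at an unadjusted p under 0.05. These too are fewer than evenly spread p-values would give on average, and they were not set against other splits. The test of whether the effect differed between the 2 lung and the 2 ovarian lines also called 0 of 4570 tiles with limma. Its smallest adjusted p was 0.931, and at an unadjusted p under 0.05 limma gave 29 tiles with the more positive difference in lung lines and 166 with the more positive difference in ovarian lines. Their total was likewise below the average from evenly spread p-values, and it was not set against other splits. In tests on simulated data, limma recovered 50% of tiles changed by 1 on the log2 scale in every line, and 100% of those changed by 4. The simulation changed many tiles at once and gave all lines equal noise. The SD of real differences ran from 2.19 points in H460 to 5.91 in A2780 over CpG-dense tiles, so recovery in the real data may be lower.

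The number of CpGs listed also differed by region between the libraries of a line. At tiles that were highly and equally methylated in both libraries, 12.7% of 1-Mb windows in OVCAR3 had a shifted share of listed CpGs, against 6.68% in H23, 6.12% in A2780 and 0.0911% in H460. In A2780, the resistant library listed more CpGs along chromosome 17 (chr17:36000001-50000000, 94.6% against 90.4%). In OVCAR3 it listed relatively fewer along chromosome 4 (chr4:15000001-43000000, 79.7% against 86.2%), chromosome 6 (chr6:1-29000000, 79.3% against 83.8%) and the end of chromosome 3 (chr3:170000001-198000000, 89.1% against 92.3%). Runs were cut where a window could not be measured, so some are parts of longer stretches. Nearly all measured windows of chr17:36000001-82000000 in A2780, and all those of chr4:1-49000000 and chr6:1-50000000 in OVCAR3, were shifted in the same direction as the run named. Among tiles in windows where the share could be measured, shifted windows held 13.9% of the changed 1-kb tiles of A2780 and 5.01% of all its tested tiles. The values were 14.2% and 5.81% in H23, and 10.6% and 11.8% in OVCAR3.

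**Figure D4:**
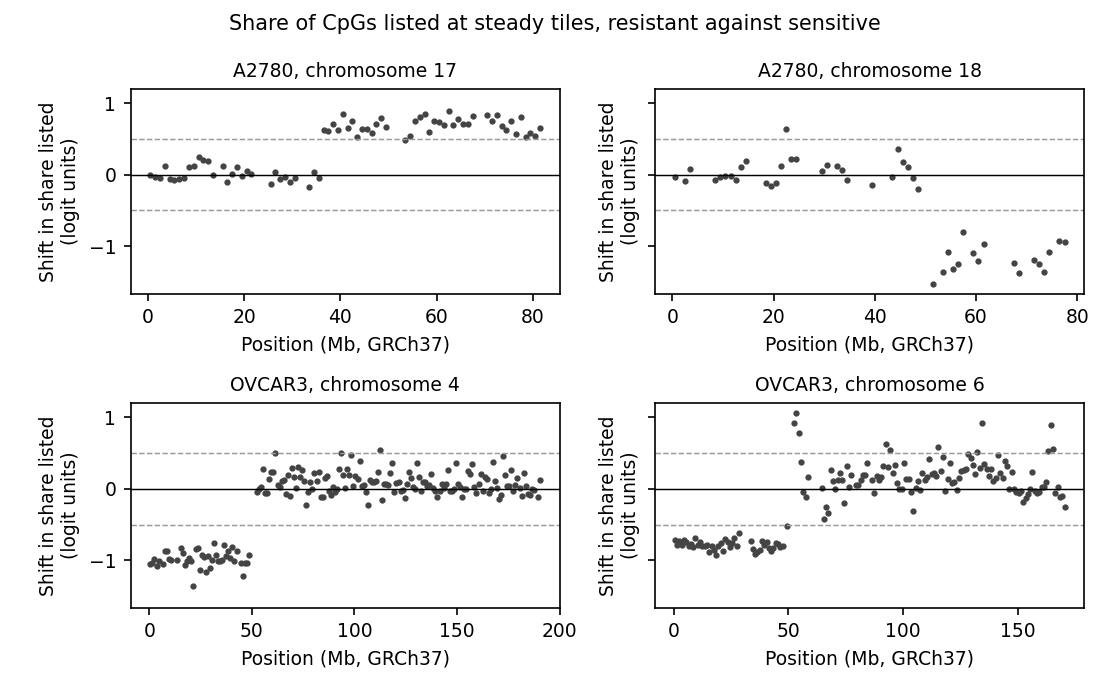
Shift in the share of CpGs listed between the resistant and the sensitive library, on the logit scale and centred on the median window, at highly methylated tiles that did not differ, with a point per 1-Mb window along chromosomes 17 and 18 of A2780 and chromosomes 4 and 6 of OVCAR3, and dashed lines at 0.5 and -0.5. Windows of chr17:36000001-50000000 in A2780 lie at a median of 0.651, and those of chr18:53000001-58000000 in A2780, chr4:15000001-43000000 and chr6:1-29000000 in OVCAR3 at -1.25, -0.961 and -0.782. These runs are cut where a window could not be measured, and shifts in the same direction lie beyond them.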

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

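The share of listed CpGs as measured here, and the tests of noise, of shared reads, of chance clustering and of copy number, were chosen only after the results they bear on were seen. A first measure of the listed share over all CpGs put 31.6% of the changed tiles of A2780, 27.7% of those of OVCAR3 and 86.7% of the A2780 windows with many rising tiles in shifted windows, and it was replaced because the listed share follows the methylation level. A first test of shared reads, by the median difference at the other end of a tile, left that cause open in A2780 and fell on its side in OVCAR3, and it was replaced by the share moving in the same direction, first at the other end and then, as ends 300 bp apart need not be fully separate, in a tile 1 kb away.

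The share of CpGs listed is a signal outside the methylation levels, and it shifted over long runs of windows in 3 lines. In A2780, chr18:53000001-58000000 was listed at 76.5% in the resistant and 92.1% in the sensitive library, a median shift of -1.25 on the logit scale. In H23, chr1:153000001-162000000 was listed at 84.4% and 93.4%, a shift of -0.786. In OVCAR3, chr4:44000001-49000000 was listed at 77.8% and 85.4%, a shift of -1.03. These are the runs with the largest shift per line, and runs were cut where a window could not be measured. In A2780 all measured windows of chr18:51000001-78000000 were shifted the same way, as were all those of chr4:1-49000000 in OVCAR3. The share of listed CpGs depends on depth, which is unknown, so copy number was not measured. None of the groups of 4 libraries or lines tested for a value far from the others (15 groups) had one.

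The higher level of the resistant OVCAR3 library was weighed first. Incomplete conversion acts on unmethylated CpGs only, so it would raise unmethylated regions by more than the 1.39 points seen over all CpGs. Tiles unmethylated in both libraries rose by a median of 0.222 points. These tiles were chosen for a mean of both libraries under 5%, so tiles raised well past that level would be missed. A broad shift of highly methylated CpGs stays open for part of the rise: tiles over 90% methylated rose by a median of 0.733 points. The rise was not confined to them. Tiles between 50 and 90% rose by a median of 4.36 points (85233 tiles) and tiles between 5 and 50% by 2.77 points (28796 tiles). Strongly changed tiles may carry part of the difference, since leaving out tiles that changed by 10 points or more lowered the mean over tiles from 1.36 to 0.980 points, between the bounds set for that test. The acquisition of resistance stays open as well and was not tested, as there is 1 library per state.

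The many changed tiles of A2780 and OVCAR3 were weighed next, where noise independent between CpGs did not account for them, since tiles called on alternate CpGs differed in the same direction at the remaining CpGs by a median of 30.7 points in A2780 and 33.5 points in OVCAR3. Such CpGs often share reads. Tiles 1 kb beyond a changed tile were therefore compared with tiles at the same level beside steady tiles. The share moving in the same direction was greater by 36.7 percentage points for higher and 27.3 for lower tiles of A2780, and by 20.9 for higher tiles of OVCAR3. Chance from few reads as the whole cause would not give this in the tiles covered. These were 1225 of 2804 higher and 352 of 1330 lower tiles of A2780, and 848 of 2201 higher tiles of OVCAR3. The other calls had no such tile and were not checked in this way. Beside lower tiles of OVCAR3, 43.1% of 248 tiles were lower too, and the median difference in that direction was -0.233 points. The excess there was 10.7 points, and 8.89 at the lowest with a chromosome left out, so such chance stays open. It also stays open for part of the other tiles. Over both directions, the median difference at the other end of a tile was 11.9 points in A2780 and 4.64 points in OVCAR3. Another line of the series mixed into the resistant library would move tiles towards it, and the largest median move was 0.925 points in A2780 and 2.13 points in OVCAR3. Copy number was judged only by the listed share, and 1-Mb windows in which that share shifted held 13.9% of the tiles in A2780 and 10.6% in OVCAR3, of 2996 and 2257 tiles in measured windows and against 5.01% and 11.8% of all tested tiles, so changed tiles of A2780 were concentrated there but most lay elsewhere, and the acquisition of resistance was not tested.

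The gathering of rising tiles in A2780 was weighed last. Chance placement of tiles with the same starting level gave as many tiles in a window in 0 of 100 draws. Copy number change of these windows cannot be told apart from a change in methylation alone: 33.3% of the measured windows, 4 of 12, had a shifted listed share at steady tiles, between the bounds set for that test, and the fullest window, chr18:22000001-23000000, was among them, while the next fullest, chr1:210000001-211000000, could not be measured. A change of whole domains in the derivative is a candidate explanation, as a hypothesis found in the same data.

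The count of CpG-dense tiles over the 4 lines was compared with other splits of the 8 libraries, of which the model could be fitted to 32. The real split called 0 tiles and the highest of the other splits called 0, so that 32 of 32 gave as many by necessity, which decides nothing. At an unadjusted p under 0.05 the real split gave 147 tiles and the highest other split 600, and 17 of 32 splits gave as many, so chance is not excluded. Among the 8 splits that part every pair of libraries, 3 gave as many and the highest other gave 240. The other splits part 2 of the pairs, and their counts followed which lines were parted. Splits that part H460 with another line gave 59 to 147 tiles. Those that part 2 of the other lines gave 226 to 600, with 600 for A2780 and OVCAR3. The SD of differences among CpG-dense tiles was 2.19 points in H460, against 4.02 in H23, 5.52 in OVCAR3 and 5.91 in A2780. Each split that parts 2 pairs has an equal fit among the others, so the 32 are not all distinct.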

How the results depend on the processing

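The alternatives without CpGs at exactly 0 or 100%, with centring, with another logit offset, without windows of shifted listing and with 3 lines over all autosomes were chosen after seeing the data. No difference in level changed sign, and the balance of higher and lower tiles turned in H23 with centring. Of 117 alternative values of the results that answer a comparison, 77 stayed within the spread or within 1.5 times the count, and 40 moved. Of 20 others, 15 moved, among them the shares of large domains, which in windows of 50 kb were lower in every library. Windows of 50 kb kept the minimum of 50 CpGs, so more stretches with few listed CpGs were left out. The shares of the 2 widths are therefore not over the same stretches. In the resistant and sensitive libraries the shares in windows of 50 kb were 17.5% and 17.3% in A2780, 7.09% and 7.15% in H460, 3.15% and 3.70% in OVCAR3, and 1.23% and 0.883% in H23. Windows with listing shifted beyond 0.3 made up 27.8% in OVCAR3, 20.3% in H23, 11.4% in A2780 and 1.23% in H460. In 5-Mb windows beyond 0.5 the shares were 9.09%, 4.35%, 3.61% and 0%. The cause was not tested except where named.

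The OVCAR3 difference was 1.01 points on CpGs listed in all 8 libraries, which also limits it to the shared part of chromosomes 1 and 2, where all CpGs give 1.28 points. It was 2.14 points without CpGs at 0 or 100%, where A2780 went from 0.210 to 0.366 and H460 from -0.137 to -0.253 points, within their spread between chromosomes. That of H23 was 0.946 and 1.13 points, set against a spread of 0.0125 points between only 2 chromosomes. The mean over 4 lines ranged from 0.428 to 0.880 points when each line was left out in turn.

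Higher and lower 1-kb tiles at 40 points numbered 780 and 370 in A2780, 16 and 14 in H23, 0 and 1 in H460, and 754 and 129 in OVCAR3. With at least 10 CpGs they were 847 and 276, 23 and 13, 0 and 1, and 681 and 118, of fewer tiles tested. With a sign-flip permutation test over CpGs they were 608 and 194, 8 and 6, 0 and 0, and 456 and 69, since tiles with few CpGs cannot reach a small p. Centred on the median difference, H23 had 66 higher and 74 lower tiles, so its excess of higher tiles depends on the centring, and A2780 had 2819 and 1319 and OVCAR3 2014 and 418.

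CpG-dense tiles at 30 points numbered 228 higher and 70 lower in A2780, 4 and 4 in H23, 0 and 0 in H460, and 149 and 16 in OVCAR3. With the sign-flip permutation test H460 had 1 higher. Tiles shared by at least 2 lines at 30 points numbered 0 higher among 4 lines, and 3 higher and 0 lower among 3 lines.

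The limma fit with the cell line as a block called 0 tiles, and without the block it called 0 (1 higher and 0 lower at an unadjusted p under 0.05). On fractions, with at least 10 CpGs, with an offset of 0.05 and with each line left out, limma also called 0, and at an unadjusted p under 0.05 the higher tiles ranged from 52 to 219 and the lower from 25 to 55. Without H23 there were 52 higher and 55 lower, and without H460 there were 219 and 25, against 108 and 39.

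Settings chosen in advance that need reads were not run, as the files hold no counts: coverage minimums, weighting by reads, thinning, added reads and the quasi-binomial model. Those that need an annotation of the build were not run either: another promoter window, the lncRNA promoters and the lists of genes. Depth, which is unknown, limits every level.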

Other observations

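The joining of shared tiles into loci and the comparison of listed shares by change were chosen after the results were seen.

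Of the 36 CpG-dense tiles that were higher in at least 2 of the lines A2780, OVCAR3 and H460, 17 lay in 2 groups. The group chr16:1034001-1272000 held 9 tiles, with a median of 30.5% in the parent and 64.8% in the derivative of A2780, and 52.6% and 81.5% in OVCAR3. The group chr10:134724001-134862000 held 8 tiles, at 33.2% and 62.5% in A2780 and 31.9% and 61.4% in OVCAR3. In H460 the medians of these groups were 75.3% and 75.1%, and 86.2% and 83.7%. The remaining 19 tiles lay alone or as neighbours of a single other tile. The tile chr6:48036001-48037000 was higher in A2780 (53.7% and 85.3%) and in H460 (32.5% and 58.9%), and was at 4.22% and 2.65% in OVCAR3.

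The chromosomes took different shares of the changes. Chromosome 18 of A2780 had 9.38 higher tiles per 1000 tested, against 2.78 over all autosomes. Of its 208 higher tiles, chr18:22000001-23000000 held 74 and chr18:23000001-24000000 held 31. Chromosomes 4, 14 and 19 of A2780 had more lower than higher tiles, at 2.62 and 1.52, 2.78 and 1.73, and 1.74 and 0.857 per 1000. On chromosome 19, 30 of the 71 lower tiles lay in chr19:22000001-23000000. In OVCAR3, chromosome 10 had 4.96 higher tiles per 1000 and chromosome 8 had 3.90, while chromosome 2 had 0.923.

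In A2780 and OVCAR3, tiles that gained methylation were also listed more fully. In A2780, tiles higher by at least 30 points had 82.8% of their CpGs listed in the resistant and 66.8% in the sensitive library, and tiles lower by as much had 66.9% and 80.8%. In OVCAR3 these shares were 79.4% and 59.4%, and 64.3% and 74.0%. Steady tiles had 90.1% and 90.5% in A2780, and 89.1% and 85.0% in OVCAR3, so part of the OVCAR3 gap was present without a change in level. In H23 the higher tiles had 65.1% and 64.9%, the lower tiles 64.9% and 74.8%, and steady tiles 81.3% and 83.7%. In H460 the 2 higher tiles had 65.0% and 70.0%, the 13 lower tiles 43.7% and 49.2%, and steady tiles 76.5% and 78.6%.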
